A study of Danio rerio with 2 samples.

How the data were processed

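The series holds 2 single-cell RNA libraries, 1 from uninjured and 1 from regenerating adult zebrafish hearts, so each group has 1 library. The fish carried tcf21:nucEGFP, a nuclear green fluorescent reporter driven by regulatory sequence of the epicardial gene tcf21, and Z-CAT, a system in which 4-hydroxytamoxifen (4-HT) triggers the loss of cardiomyocytes. Per the labels' protocols, the treated fish were kept for 12 hours in 1 µM 4-HT, hearts were dissociated with the collagenase blend Liberase, and live EGFP-positive cells were sorted by flow cytometry and loaded on a droplet system that reads the 3' ends of transcripts. The time between treatment and dissection and the number of hearts pooled are not given in the sources used here.

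For each library the authors deposited a sparse matrix of counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Per the submitters' processing notes, the reads were processed with Cell Ranger 3.1.0 and the build was GRCz11, and a settings record beyond that is not given in the sources used here. Both tables share 32058 gene rows, of which 28988 were matched to a table of gene names by identifier, and 6690 rows carry a symbol that an earlier row already uses. Rows that share a symbol were kept apart by identifier. EGFP is a row of both tables. Droplet counts of near-identical gene copies can be split or lost by the counting step, so values of paralogs such as the hsp70 and ptgdsb genes are less certain than the others.

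Cells were kept with at least 500 detected genes and at most 20 percent of UMIs in the 13 mitochondrially encoded genes. These filters removed 208 of 4250 barcodes from the uninjured library and 479 of 4947 from the regenerating one. Scrublet (in scanpy, expected rate 0.04) then marked 2 cells in each library, 0.0495% and 0.0448%. At so low a share the caller has not worked, and doublets have to be taken as still present among the 4040 and 4466 cells kept. Cells were scaled, log-transformed and clustered with both libraries together (2000 variable genes without hapln1a and hapln1b, 30 principal components, 15 neighbours, Leiden resolution 0.5), with no batch integration, which gave 11 clusters.

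Clusters were named from 14 marker lists fixed before the data were examined. A cluster took the name of another type where at least 3 of its markers were among the 20 genes with the highest fold over the other cells (at least 50 CPM) and its markers summed to more CPM than the epicardial ones. It stayed unnamed where another type had more markers among its first 10 genes than the epicardial list had, and was otherwise called epicardial-like where at least 3 epicardial markers were detected. The other named classes met that last condition too, with 14 to 16 of 18 epicardial markers detected. Epicardial-like was thus the name of any cluster that no other list claimed or left unnamed. The naming rule was set after the clusters had been seen. An earlier version of it, without the step on the first 10 genes, counted cluster 4 as epicardial-like, so the results were also computed with cluster 4 included. Few cells can decide a name: in cluster 4, 99 of 656 regenerating cells held any erythrocyte-marker UMI, and 1 cell held 2605 of the 2718.

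UMIs of the epicardial-like cells were summed per library and divided by their total to give CPM, the counts scaled to a common total. With 1 library per group no test across samples is possible, and no p-value or standard error is given. A gene was called higher or lower by a rule of size alone: at least 2-fold on CPM plus a pseudocount of 1, at least 20 CPM in either library and at least 50 UMIs over both. Counts carry exact Poisson intervals, shares Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95% and all covering counting error only. A gene with 0 UMIs in a library was set at a floor of 3 UMIs of that library, 0.0883 CPM in uninjured and 0.0614 CPM in regenerating epicardial-like cells. For each of 39 gene lists fixed beforehand, the median log2 ratio of the members with at least 50 UMIs was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Of 1154 symbols in the lists, 37 had no row. Shares of cells with a UMI were taken after each cell was thinned to 2000 UMIs, with shallower cells left out. Genes that go with hapln1a were found by comparing, within each library, thinned cells with and without a hapln1a UMI, at a minimum of 1.5-fold in both libraries.

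Named genes follow a rule fixed before the data were examined. They are the 12 highest and 12 lowest log2 ratios among genes past the expression minimum, up to 4 measured members of each list with the largest absolute ratio and at least 10 CPM, a fixed set (hapln1a, hapln1b, tcf21, tbx18, wt1a, wt1b, aldh1a2 and the reporter), and, for the comparison by hapln1a, the 12 highest and 8 lowest in both libraries. Mitochondrial, ribosomal protein and clone-style names were only counted. Not every gene that this rule names is reported here. Alternatives set beforehand were TMM and median-of-ratios scaling, per-cell means, totals without mitochondrial and ribosomal protein genes, all kept cells, all barcodes, thinned cells, other filters, pseudocounts, minimums, resolutions and feature sets. Alternatives chosen after seeing the data were the inclusion of cluster 4 and the removal of the highest 4 percent of doublet scores.

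The comparison was tested on simulated data drawn from the means of both libraries, in which 2891 genes passed the expression minimum. Of simulated 3-fold differences 64 of 66 (97.0%) were called in the right direction, of 4-fold differences 67 of 67 and of 1.5-fold differences 0 of 67. Changed genes were counted whether or not they passed the minimum. Of the genes that passed it, 2693 were unchanged and none of these was called (0), and 95.3% of the intervals held the simulated ratio. The simulation holds counting error, but no variation between animals and no shift of scale shared by most genes. Its lack of false calls therefore says nothing about calls made by such a shift. Work was done in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9. An mCherry row occurs in the uninjured table alone and entered no comparison.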

Results

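The epicardium is the cell layer that covers the heart, and the gene tcf21 marks it and many of the cells it gives rise to. Nuclei labelled by tcf21:nucEGFP were used to sort living epicardial cells from uninjured hearts and from hearts regenerating after 4-HT, which removes cardiomyocytes in these fish. The uninjured library holds 4250 barcodes with 35738213 UMIs and the regenerating library 4947 barcodes with 59381679 UMIs. After filtering, 4040 uninjured cells with a median of 8025 UMIs and 4466 regenerating cells with a median of 12649.5 UMIs remained. Each group has 1 library, so no difference has a replicate check, and all intervals given are 95% intervals of counting error. Pairs of values are given with the uninjured library first. The uninjured library is labelled untreated and the regenerating library treated with 4-HT. Differences between fish, days or handling, or from 4-HT exposure itself, cannot be told apart from those of regeneration in this design.

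Most sorted cells were called epicardial-like in both libraries, the name left for clusters that no other marker list claimed. The class took 3854 of 4040 uninjured cells (95.4%, 94.7 to 96.0) and 3729 of 4466 regenerating cells (83.5%, 82.4 to 84.6). Mural or smooth muscle-like cells, led by myh11a, rgs5a and acta2, made up 2.23% of uninjured and 1.37% of regenerating cells. Cardiomyocyte-like cells, led by cmlc1 and myl7, made up 1.58% and 0.112%, which is 64 and 5 cells, and macrophage or monocyte-like cells made up 0.767% and 0.336%. The cardiomyocyte-like uninjured cells also held tcf21 at 6009 CPM and EGFP at 7424 CPM, close to the epicardial-like levels of 6648 and 7493. All are shares of cells passed by an EGFP sort. Cluster 4 stayed unnamed and held 656 regenerating cells (14.7%) and 1 uninjured cell (0.0248%). The epicardial-like share of uninjured cells was 15.8% with at least 1000 genes per cell and 46.0% with called doublets kept, and the epicardial-like share of regenerating cells was 98.2% with cluster 4 included and 49.8% without the highest 4 percent of doublet scores.

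The libraries shared few clusters. Uninjured epicardial-like cells lay mostly in cluster 2 (1820 cells, led by phlda2 and the small heat shock gene hspb8), cluster 3 (1361 cells, led by the prostaglandin D synthase-type gene ptgdsb.2) and cluster 5 (501 cells). Regenerating ones lay mostly in cluster 1 (2807 cells, led by ogna, mgp and vcana), cluster 6 (484 cells, led by the proliferation genes mki67, top2a and pcna), cluster 7 (189 cells, led by the acute phase gene saa and the interferon-induced genes isg15 and rsad2) and cluster 5 (137 cells). Cluster 5, with high podxl and jam2b, was the one epicardial-like cluster with at least 100 cells of each library. A cluster that comes mostly from 1 library may be that library and not a cell type.

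The first comparison asks how the transcripts of epicardial-like cells differ between regenerating and uninjured hearts. Fibrillar and associated collagens had the highest median of the measured lists in the regenerating library. Of 18 measured members, 16 were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.13 (percentile 100 of random lists). col12a1a was at 24.8 and 1891 CPM, a ratio of 76.3 (71.3 to 81.8), and col12a1b at 0.736 and 333 CPM, a ratio of 452 (306 to 699). col1a2, a chain of type I collagen, was at 675 and 4260 CPM. col11a1a had 0 UMIs in uninjured cells and 37.9 CPM in regenerating ones, 429-fold above the floor of 3 UMIs, with 349 as the lower bound of its exact interval. Matrix glycoproteins and proteoglycans had 11 of 32 higher and 0 lower (median 1.41, percentile 100), among them the periostin gene postnb at 168 and 2842 CPM (16.9-fold, 16.5 to 17.4) and lumican (lum) at 5.53 and 166 CPM. Among matrix remodelling enzymes and inhibitors 10 of 28 were higher and 2 lower (median 0.91). The collagen crosslinker loxa was 20.7-fold higher, while a timp4 gene (ENSDARG00000100795) was 49.1-fold lower.

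The activated epicardium, mesenchymal, epithelial-layer and actin lists also lay above the middle 95 percent of random lists of their size. Of 22 genes of the activated epicardium list, 11 were higher and 1 lower (median 1.51, percentile 100). Mesenchymal or fibroblast genes had 10 of 21 higher (median 1.15), and those of the epithelial layer 8 of 17 higher and 1 lower (median 1.04), with the annexin anxa2a at 1122 and 4668 CPM and the tight junction gene cldn11a at 0.736 and 55.0 CPM. Epithelial-layer members under the expression minimum went both ways. jam2b was 5.82-fold lower, krt5 had 110 and 0 UMIs, and alcama was 8.94-fold higher. Cluster 5, with high podxl and jam2b, made up 12.4% of uninjured and 3.07% of regenerating cells. The list median therefore does not show a larger share of such cells. The actin and contraction list had 11 of 37 higher and 1 lower (median 0.87). In it, acta2 was 24.2-fold and tagln 8.56-fold higher, and both also mark mural cells, whose list had a median of 0.50 with rgs5a 20.7-fold lower. Without the highest 4 percent of doublet scores the acta2 log2 ratio was 2.01 against 4.38. That setting also left 2073 regenerating cells unnamed through 1 mural marker, so the change cannot be laid to doublets. Secreted growth factors went both ways (9 of 35 higher, 4 lower), and the median of secreted growth factors was 0.28, or -0.12 with TMM. The midkine gene mdka was at 629 and 8359 CPM, and its paralog mdkb at 652 and 17.5 CPM.

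The cell cycle lists had high medians in the regenerating library, though few members passed the rule of size. The S phase list had a median log2 ratio of 1.54 (5 of 29 higher, 1 lower) and the G2 and M phase list 1.75 (2 of 37 higher, 0 lower, all 37 with a positive ratio). Most of these genes lay under the expression minimum. mki67, a marker of cycling cells, was at 1.00 and 12.8 CPM. The proliferative cluster 6 held 584 of the 627 regenerating UMIs of this gene (66.8 CPM), against 1.11 CPM in cluster 1. After thinning, 4 of 3840 uninjured cells (0.104%, 0.0284 to 0.266) and 58 of 3704 regenerating cells (1.57%, 1.19 to 2.02) held a mki67 UMI. Thinned shares were 8.88% in cluster 6 and 0.143% in cluster 1 of the regenerating library. Unthinned shares over the class were 0.182% and 4.83%. In mural or smooth muscle-like cells 0 of 52 and 1 of 56 thinned cells held one. Of 98 measured nuclear genes of oxidative phosphorylation, 65 were higher and 0 lower (median 1.37, percentile 100). Glycolysis, with 6 of 23 higher and 1 lower (median 0.54, percentile 75.8), and mitochondrially encoded genes, with 2 of 13 higher and 0 lower (median 0.73, percentile 88.55), lay inside the range of random lists. The secretory folding list had 17 of 35 higher and 1 lower (median 0.98), with the collagen chaperone fkbp10b 7.03-fold higher. Cytosolic ribosomal proteins had a median of -0.13.

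Stress and immediate early genes had the lowest median of the measured lists in the regenerating library. Of 41 measured members 28 were at least 2-fold lower and 0 higher (median -1.64, percentile 0). The AP-1 genes fosl1a, fosb and fosab were 12.5-fold, 12.2-fold and 7.98-fold lower, and atf3 was 11.9-fold lower. These genes also respond to tissue dissociation. The list of inflammatory mediators had 8 of 26 lower and 3 higher (median -0.54), with the chemokine cxcl18b at 3491 and 623 CPM, and saa in the opposite direction at 3.15 and 186 CPM. The 189 cells of cluster 7 held 8206 of the 9082 regenerating saa UMIs (3144 CPM), against 21.3 CPM in cluster 1. The median of inflammatory mediators was 0.041 without the highest 4 percent of doublet scores, a setting that also left 2073 regenerating cells unnamed. Other lower genes were the prostaglandin D synthase-type genes ptgdsb.2 (233 and 1.25 CPM) and ptgdsb.1, hsd11b2, which inactivates cortisol (637 and 28.6 CPM), the lipoprotein lipase gene lpl (56.7 and 2.46 CPM), the glycolysis regulator pfkfb3 (82.1 and 4.16 CPM) and the retinol carrier rbp4 (7913 and 1315 CPM). Of 9 measured cardiomyocyte markers 1 was at least 2-fold lower, myoglobin (mb) at 29.8 and 3.62 CPM, and 0 were higher (median -0.96, percentile 0), while the list summed to 439.7 and 426 CPM, of which tpm4a made up 371 and 416. Of 7 endothelial or endocardial markers 0 were lower and 1 was higher, nfatc1 at 14.2 and 32.4 CPM (2.28-fold). Their median was -0.92, and 0.37 with at least 1000 genes per cell, and the list summed to 41.8 and 44.6 CPM.

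**Figure D1:**
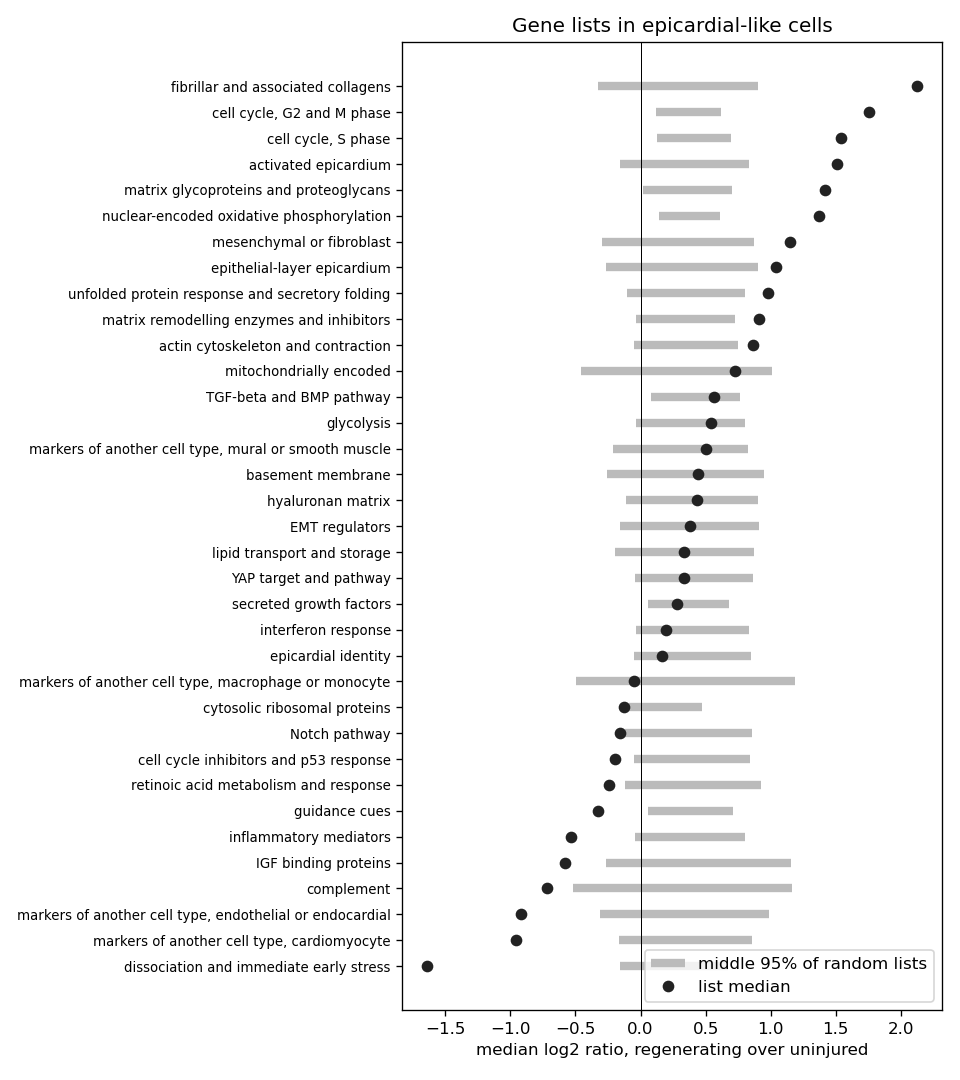
Median log2 ratio of CPM plus 1, regenerating over uninjured epicardial-like cells, for the gene lists with at least 5 measured members, drawn with the middle 95 percent of random lists of the same size. Fibrillar collagens (2.13) and the cell cycle lists lie highest and the stress list (-1.64) lowest.

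In all, 1005 genes were at least 2-fold higher and 404 at least 2-fold lower among 3366 genes past the expression minimum, so 71.3% of the genes called either way were higher. Mitochondrial, ribosomal protein and clone-style names made up 69 of the higher and 56 of the lower genes. The scale behind this split is not settled by the data. The median log2 ratio of all 3366 genes was 0.50 on CPM, 0.02 with TMM and -0.03 with median-of-ratios scaling. The counts were 549 higher and 638 lower with TMM (46.3% higher) and 504 and 674 with median-of-ratios (42.8%). The collagen, cell cycle, oxidative phosphorylation and stress lists kept their direction under each of these scalings.

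Epicardial identity genes went both ways (5 of 20 higher, 1 lower, median 0.17, percentile 14.5, and -0.22 with TMM). tcf21 (ENSDARG00000036869) was 3.04-fold lower, at 6648 and 2184 CPM. It was also lower outside the class, at 3555 and 750.3 CPM in macrophage or monocyte-like cells and 3338 and 1170.0 CPM in mural or smooth muscle-like cells. EGFP, the reporter driven by tcf21 sequence, was at 7493 and 9365 CPM, a ratio of 1.25 (1.24 to 1.26) whose direction turned with TMM and median-of-ratios scaling. aldh1a2, which makes retinoic acid, was 3.36-fold higher (3.24 to 3.50) at 92.2 and 310 CPM. Cluster 5 held 2774 of the 3133 uninjured aldh1a2 UMIs, and within it the gene was at 482 and 747 CPM. Uninjured cells of clusters 2 and 3 were at 11.5 and 11.0 CPM, and regenerating cells of cluster 1 at 294. aldh1a2 was lower with at least 1000 genes per cell, where clusters with 1513 and 1121 uninjured cells stayed unnamed. gata5 was 4.54-fold higher. tbx18 was at 101 and 107 CPM, wt1a at 5.09 and 4.14 and wt1b at 13.5 and 9.50.

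Within cluster 5, where 501 uninjured and 137 regenerating cells were compared, the cluster mix cannot set the ratios. There 426 of 2782 genes were higher and 250 lower, and 332 and 162 of these had the same call over all epicardial-like cells. Among the 2782 genes, 696 were called higher and 354 lower over all epicardial-like cells, which include cluster 5. Most of those calls were therefore not met within the cluster. The fibrillar collagens (12 of 14 higher, median 1.55), activated epicardium (9 of 17 higher, median 1.16), secretory folding (11 of 33 higher, median 0.93) and oxidative phosphorylation (28 of 85 higher, median 0.73) lists were high here too. The stress list was lower, with 10 of 38 lower and 1 higher (median -0.62). Of 9 complement genes 3 were higher and 1 lower in cluster 5 (median 0.71). Over all epicardial-like cells 1 was higher and 3 were lower (median -0.72). That median was 0.0065 without the highest 4 percent of doublet scores, where 2073 regenerating cells stayed unnamed. Inside the range of random lists in cluster 5 were the actin list (4 of 30 higher, 1 lower, median 0.02), the epithelial-layer list (5 of 14 higher, median 0.30, percentile 88.6) and inflammatory mediators (2 of 18 higher, 2 lower, median -0.23). Cell cycle lists had too few measured members. Outside the class, col12a1a was at 0 and 1356 CPM in macrophage or monocyte-like cells and 73.3 and 523 in mural or smooth muscle-like cells. There postnb was at 58.1 and 1784 CPM and at 99.2 and 259 CPM. In cardiomyocyte-like cells, 5 of them regenerating, col12a1a was at 7.56 and 12.0 CPM and postnb at 81.2 and 95.9. Free RNA shared within a library, or doublets, may thus add to these genes in cluster 5 too, which was not tested.

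The series names hapln1, so hapln1a (ENSDARG00000089769) was followed on its own. It encodes a link protein that ties hyaluronan to proteoglycans in the matrix. In uninjured epicardial-like cells it was at 202 CPM and in regenerating ones at 291 CPM, a hapln1a CPM ratio of 1.44 (1.40 to 1.48) under the naming rule set after the clusters were seen. That is the size of the shared shift in scale: 50.7% of the 3366 genes had a lower ratio. With TMM the ratio was 1.09 and with median-of-ratios 1.07. It was 1.28 over all kept cells, 1.29 with cluster 4 included, 8.17 with at least 1000 genes per cell, between 4.14 and 4.32 under 3 other settings that took a large uninjured cluster out of the class, and 0.945 without the highest 4 percent of doublet scores, where 1 mural marker left 2073 regenerating cells unnamed. No direction of hapln1a between the libraries is therefore drawn. Its paralog hapln1b was at 35.7 and 25.3 CPM.

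**Figure D2:**
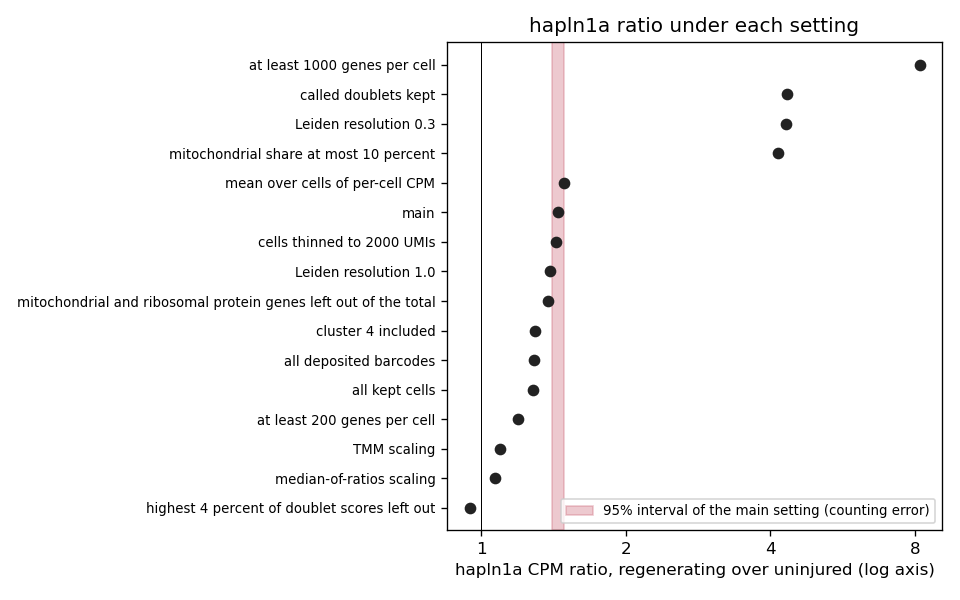
Ratio of hapln1a CPM, regenerating over uninjured, on a log axis for each processing setting. The band is the 95% interval of counting error of the main setting, and no interval is drawn for the others. The main value is 1.44, and the settings run from 0.945 to 8.17.

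After thinning to 2000 UMIs, 781 of 3840 uninjured epicardial-like cells (20.3%, 19.1 to 21.6) and 1156 of 3704 regenerating cells (31.2%, 29.7 to 32.7) held a hapln1a UMI, with 14 and 25 shallower cells left out. Unthinned shares were 35.4% and 54.3%. In mural or smooth muscle-like cells, with median depths of 2114.5 and 4564 UMIs against 8108 and 12533, thinned shares were 5.77% (3 of 52) and 0 of 56 cells, whose upper bound is 6.38%. Other classes lay higher in the uninjured library, at 23.8% of cardiomyocyte-like cells (15 of 63, 14.0 to 36.2) and 16.1% of macrophage or monocyte-like cells (5 of 31, 5.45 to 33.7), with median depths of 7251 and 12741 UMIs. The uninjured epicardial-like share lies inside both intervals, so background in it is not bounded by the mural share alone. In the regenerating library 1 of 5 and 0 of 15 such cells held a UMI. The uninjured share was 3.38% with at least 1000 genes per cell, so these shares carry the same limits as the ratio.

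Within each library hapln1a differed widely between the epicardial-like clusters with at least 100 of its cells. In uninjured cells it was at 395 CPM (385 to 405) in cluster 2, 135 in cluster 8, 80.3 in cluster 3 and 8.51 (6.30 to 11.3) in cluster 5. In regenerating cells it was at 362 CPM (356 to 368) in cluster 1, 189 in cluster 7, 91.2 in the proliferative cluster 6 and 20.9 (14.7 to 28.8) in cluster 5. Smaller groups of cells reached higher levels, with 752 CPM (568 to 976) in 10 uninjured cells of cluster 7 and 748 CPM (546 to 1001) in 12 regenerating cells of cluster 8. Regenerating cells were at 232 CPM in cluster 2 (79 cells) and 173 in cluster 3 (21 cells), and uninjured cells at 219 in cluster 1 and 148 in cluster 6 (6 cells each). In the clusters with at least 100 cells, thinned shares of cells with a UMI followed the same order, from 1.21% in cluster 5 to 33.1% in cluster 2 of the uninjured library and from 1.49% to 36.8% in clusters 5 and 1 of the regenerating one. hapln1a and hapln1b were left out of the clustering. With both among its features, the hapln1a CPM of the highest uninjured epicardial-like cluster was 183. In that setting a cluster with 1804 uninjured cells stayed unnamed and was not among the clusters ranked. With each library clustered alone, the hapln1a CPM of the highest regenerating epicardial-like cluster was 654. With 3000 variable genes, the hapln1a CPM of the lowest regenerating epicardial-like cluster was 11.0.

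**Figure D3:**
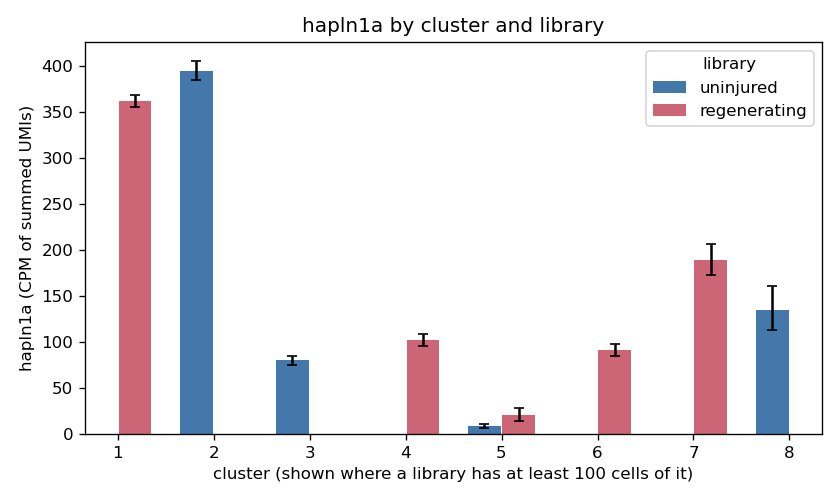
hapln1a CPM per cluster and library, for clusters with at least 100 cells of that library, with exact Poisson 95% intervals. Cluster 4 (102 in the regenerating library) stayed unnamed and is not part of the epicardial-like class. Cluster 2 of the uninjured library (395) and cluster 1 of the regenerating library (362) stand highest of those drawn and cluster 5 lowest in both (8.51 and 20.9).

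The last comparison asks which genes go with hapln1a inside a library. Among 2404 genes, 55 were at least 1.5-fold higher in cells with a hapln1a UMI in both libraries and 18 were lower in both. Independent lists of the same sizes would share 16.2 and 1.13. The matrix genes vcanb (versican), mgp, dpt, col8a1b, adamtsl3 and hapln1b were among the 12 highest in both. vcanb was 3.53-fold higher (2.59 to 4.81) in uninjured and 2.63-fold higher (1.94 to 3.56) in regenerating cells. cd74a, an antigen presentation gene that also marks macrophages, was 4.62-fold and 3.13-fold higher and the cytokine il11b 3.105-fold and 2.76-fold higher. s100a10a, steap4, efna1b and cemip, which breaks down hyaluronan, were lowest, with cemip at 0.356 and 0.178 times. Fibrillar collagens had medians of 0.84 and 0.44 and basement membrane genes 0.70 and 0.44, each at percentile 100, while oxidative phosphorylation had -0.06 and -0.29. The stress list was also high, with medians of 0.33 and 0.16 at percentiles 99.9 and 98.9 and 7 and 1 of 37 members higher. The hyaluronan matrix list, with 2 of 5 higher and 1 lower in each library, had medians of 0.06 and 0.12 at percentiles 26.0 and 54.7, inside the range of random lists. Many of the gene calls go with the clusters: compared within clusters, 17 genes were higher and 1 lower in both libraries. The list medians are not given within clusters.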

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

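Of the tests in this part, the ones within cluster 5 and both tests on hapln1a were chosen after the results were seen, and those on mural-like cells and on abundant genes before.

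A transgene row named mCherry occurs in the table of the uninjured library alone, which no comparison used. It holds 10490 UMIs there, in 3259 of 4250 barcodes (76.7%, 75.4 to 77.9). The regenerating table has no such row, so no count of 0 was measured there and the row cannot be compared. Whether the counting of the libraries differed in other ways is not known from these data. No explanation for it was tested.

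2 genes went with hapln1a in opposite directions in the 2 libraries, and that difference was not tested. angptl2b was 0.470 times as high in uninjured cells with a hapln1a UMI as in those without and 2.105 times as high in regenerating ones. stim1a was at 1.54 (0.996 to 2.33) in uninjured and 0.591 in regenerating cells.

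Stress and immediate early genes were lower in the regenerating library (median log2 ratio -1.64). A different mix of clusters as the whole cause is argued against by cluster 5 alone, where the median was -0.62 (-0.81 to -0.14 over 38 members). A difference in handling between the libraries would reach every cell, and in mural or smooth muscle-like cells the median was -1.81 (-2.55 to -1.36 over 32 members), as that explanation predicted for them. Macrophage or monocyte-like cells had -1.06, and the -0.62 of cluster 5 was a smaller drop. The values thus do not show a drop of 1 size in every cell, and no prediction on handling was set for cluster 5. A response to injury that reaches all cell types, or free RNA shared within a library, may give the same values, so these stay open beside handling.

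On CPM, tcf21 was lower in regenerating epicardial-like cells while EGFP was not, with a ratio of 1.25. The direction of EGFP turned with TMM and median-of-ratios scaling. A different mix of clusters as the whole cause is argued against by a tcf21 ratio of 0.438 (0.424 to 0.451) within cluster 5. A loss shared by abundant genes of the uninjured library cannot be told apart from a loss of its own: 38 genes at 2000 CPM or more had a median log2 ratio of -0.54 (-1.60 to -0.20), an interval that reaches close to the tcf21 value of -1.61, and many of those genes belong to the stress list. tcf21 was also 4.74-fold lower in macrophage or monocyte-like and 2.85-fold lower in mural or smooth muscle-like cells. EGFP went both ways there, with ratios of 0.771 (0.705 to 0.842) and 2.02 (1.84 to 2.21). In cardiomyocyte-like cells, only 5 of them regenerating, tcf21 was 7.48-fold lower and the EGFP ratio was 0.379. A part of the tcf21 difference shared by the whole library, free RNA included, therefore stays open. A difference in tcf21 between regenerating and uninjured epicardium stays open beside it and untested, and the EGFP sort and the stability of the reporter could keep EGFP in place.

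The hapln1a CPM ratio was 1.44 in epicardial-like cells, but 1.09 with TMM, 1.07 with median-of-ratios and between 0.945 and 8.17 across the settings, so no direction is drawn. A shift of the scale that most genes share may account for it, since the log2 ratio of hapln1a lay 0.022 above the median of 3366 genes (-0.02 to 0.07). Thinning every cell to the same number of UMIs gave a ratio of 1.43 (1.35 to 1.52), but it leaves the expected CPM as it was, so it decides nothing about the deeper sequencing of that library, which stays open. Which scale is right is not known from these data, and a biological difference between the groups stays open.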

How the results depend on the processing

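The inclusion of cluster 4 and the removal of the highest 4 percent of doublet scores were chosen after seeing the data. No paired analysis was possible because each group has 1 library and no result comes from a test, and no library was left out. Depth limits the shares of cells and the genes near the expression minimum, where most cell cycle genes lie.

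The counts of genes at least 2-fold higher and lower (1005 and 404) were 549 and 638 with TMM scaling, 504 and 674 with median-of-ratios scaling, 533 and 248 with a 50 CPM minimum and 2515 and 867 with no CPM minimum. Scaling shifts all genes and the minimum sets how many can be counted. They stayed within 1.5 times under the other settings.

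The hapln1a CPM ratio (1.44) was 1.09 with TMM, 1.07 with median-of-ratios, 1.38 without mitochondrial and ribosomal protein genes in the total, 1.48 as a mean over cells, 1.28 over all kept cells, 1.29 over all barcodes, 1.29 with cluster 4 included, 1.39 at Leiden resolution 1.0, 1.19 with at least 200 genes per cell, 4.31 at Leiden resolution 0.3, 4.32 with called doublets kept, 4.14 with a mitochondrial share of at most 10 percent and 8.17 with at least 1000 genes per cell. It reversed to 0.945 without the highest 4 percent of doublet scores.

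The epicardial-like share of uninjured cells (95.4%) was 85.7% with 3000 variable genes, 47.7% at Leiden resolution 0.3, 89.8% at 1.0, 15.8% with at least 1000 genes per cell, 91.6% with at least 200, 46.0% with called doublets kept and 52.0% with a mitochondrial share of at most 10 percent. The epicardial-like share of regenerating cells (83.5%) was 88.3%, 81.0%, 64.8%, 87.6%, 73.4%, 79.8% and 80.8% in the same order, 98.2% with cluster 4 included and 49.8% without the highest 4 percent of doublet scores. The naming rule's own construction made most of these moves. 5 or 6 cardiomyocyte markers among the first 10 genes of a large cluster left uninjured cells unnamed: 1991 at Leiden resolution 0.3, 1513 with at least 1000 genes, 2058 with called doublets kept, 1808 with the mitochondrial limit and 1804 with hapln1a and hapln1b among the features. 1 mural marker did so for 1121 further uninjured cells with at least 1000 genes, and for 2073 regenerating cells without the highest 4 percent of doublet scores.

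The thinned share of uninjured epicardial-like cells with a hapln1a UMI (20.3%) was 9.001% at Leiden resolution 0.3, 21.8% at 1.0, 3.38% with at least 1000 genes per cell, 9.05% with called doublets kept, 10.8% with a mitochondrial share of at most 10 percent, 13.8% thinned to 1000 UMIs, 24.6% thinned to 3000 and 35.4% unthinned. The share of regenerating epicardial-like cells with a hapln1a UMI (31.2%) was 26.6% with at least 200 genes per cell, 28.1% with cluster 4 included, 22.2% without the highest 4 percent of doublet scores, 20.4% thinned to 1000 UMIs, 36.4% thinned to 3000 and 54.3% unthinned.

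The genes that go with hapln1a and were higher in both libraries (55) numbered 34 at Leiden resolution 0.3, 11 with at least 1000 genes per cell, 26 with called doublets kept, 35 with a mitochondrial share of at most 10 percent, 83 without the highest 4 percent of doublet scores, 85 thinned to 1000 UMIs, 6 at a fold minimum of 2 and 17 within clusters. Genes lower in both (18) numbered 8 at a fold minimum of 2, 10 with a mitochondrial share of at most 10 percent and 1 within clusters. Among clusters with at least 100 cells of a library, the hapln1a CPM of the highest uninjured epicardial-like cluster (395) was 339 with 3000 variable genes, 502 with each library clustered alone and 183 with hapln1a and hapln1b among the features. The hapln1a CPM of the highest regenerating epicardial-like cluster (362) was 302, 654 and 325 in the same order, and the hapln1a CPM of the lowest regenerating epicardial-like cluster (20.9) was 11.0 with 3000 variable genes and 11.8 with hapln1a and hapln1b among the features.

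Calls that reversed did so mostly where the class lost uninjured cells, and the cause was not tested. The log2 ratio of aldh1a2 (1.74) was -0.50 with at least 1000 genes per cell. With Leiden resolution 0.3, at least 1000 genes, called doublets kept and a mitochondrial share of at most 10 percent, in that order, col18a1b (-1.11) was 0.37, 1.22, 0.36 and 0.25, hey1 (-1.92) was 0.16, 0.057, 0.18 and 0.025, and the Notch pathway median (-0.16) was 0.50, 0.42, 0.49 and 0.47. The endothelial or endocardial marker median (-0.92) was 0.087, 0.37 and 0.072 under the first 3 of these, and cd74a (-1.63) was 0.38 at Leiden resolution 0.3, 0.38 with called doublets kept and 0.17 with the mitochondrial limit. c4b (-1.26) was 0.035 over all barcodes, 0.020 over all kept cells, 0.37 with at least 200 genes and 0.89 without the highest 4 percent of doublet scores, where the median of inflammatory mediators (-0.54) was 0.041 and the complement median (-0.72) was 0.0065. The median of cell cycle inhibitors and p53 response genes (-0.19) was 0.28 with at least 1000 genes, and the median of guidance cues (-0.33) was 0.13 in thinned cells, where 6 lists in place of 11 lay below the middle 95 percent of random lists. Calls here are named genes at least 2-fold apart and lists outside the middle 95 percent of random lists, and the others kept their direction under each setting run. Lists inside that range are not covered: the medians of epicardial identity, EMT regulators, secreted growth factors, the interferon response, macrophage or monocyte markers and mural or smooth muscle markers changed sign under at least 1 setting.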

Other observations

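Cluster 4, kept unnamed, made up 14.7% of regenerating cells and was compared with the epicardial-like cells of the same library. Its genes were chosen after their values were seen. The chemokine cxcl8b.1 was at 335 against 12.0 CPM (27.8-fold, 25.5 to 30.4), the complement genes c4b at 885 against 91.2 and c3a.1 at 112 against 15.4, the hormone gene hamp (hepcidin) at 38.7 against 2.87 and the leptin gene lepa at 156 against 18.3. Of 9 complement genes 5 were at least 2-fold higher in the cluster (median log2 ratio 1.09). Inflammatory mediators had 4 of 25 higher and 2 lower (median 0.38, percentile 100), the interferon list 0 of 20 higher and 1 lower (median -0.49) and the stress list 0 of 41 either way (median 0.37, percentile 100). Hepatocyte markers summed to 1659.7 CPM in the unnamed cells and 473 CPM in the epicardial-like cells of both libraries, and 1 of them, tfa, was at 541 CPM in regenerating epicardial-like cells. acta2 was at 2.69 against 143 CPM and 10 of 18 fibrillar collagens were at least 2-fold lower (median -1.03), while matrix remodelling enzymes had 4 of 26 lower (median -0.18, percentile 87.8). The G2 and M phase list had 2 of 36 lower (median -1.78) against cells that include the proliferative cluster 6. mki67 was at 1.51 CPM in cluster 4, 1.11 in cluster 1 and 66.8 in cluster 6. hapln1a was at 102 CPM in the cluster, and 71 of 655 thinned cells (10.8%, 8.56 to 13.5) held a UMI. tcf21 was at 2000 CPM and EGFP at 9341 CPM, against 2184 and 9365 in the epicardial-like cells. The haemoglobin gene hbaa1, at 78.8 against 2.70 CPM, rests on few cells, since 1 cell held 2605 of 2718 erythrocyte-marker UMIs.

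Of the other lists, some went both ways and some had low medians in the regenerating library. In the hyaluronan matrix list 3 of 14 were higher and 1 lower (median log2 ratio 0.43), with vcana 16.3-fold and ptx3a 18.2-fold higher. Genes of retinoic acid metabolism had a median of -0.24 (4 of 16 higher, 2 lower, percentile 0.74), with dhrs3b at 1.53 and 33.5 CPM. TGF-beta and BMP genes had 8 of 33 higher and 2 lower (median 0.57), with id1 6.49-fold higher and bmp4 at 16.6 and 0.369 CPM. IGF binding proteins had 1 of 6 lower and 0 higher (median -0.58, percentile 0.37, 1 with a positive ratio), with igfbp2a at 25.2 and 0.655 CPM. Within cluster 5, 5 genes were higher in the regenerating library although lower over all epicardial-like cells: cxcl8b.1, si:ch73-335l21.4, RF00009, c4b and zgc:153911, named after their values were seen. For c4b the lower overall value depends on the cells taken: its log2 ratio was 0.020 over all kept cells, 0.035 over all barcodes, 0.37 with at least 200 genes per cell and 0.89 without the highest 4 percent of doublet scores.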
